A study of Mus musculus with 4 samples.

How the data were processed

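Expression was profiled in mouse long-term haematopoietic stem cells sorted 6 months after transplantation of marrow cells that had received 0, 0.02, 0.1 or 0.5 Gy of γ-irradiation. Each of the 4 doses was represented by 1 array, and the 4 arrays were grouped by the dose the labels give. Biotin-labelled cDNA was made from total RNA with an Affymetrix whole-transcript labelling kit, per the labels. The deposited values are log2 intensities, 1 per probe set defined by an Entrez gene. The base 2 was inferred from their range of 1.22 to 13.0 and is not stated. The labels name Partek as a processing tool of the authors without its role or version. Background correction, normalization and annotation build are not given in the sources used here. The arrays had near-equal medians (4.01 to 4.07). Array data carry no read depth, so the number of arrays sets the precision.

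Of 25206 probe sets, 23185 carried a gene symbol in the platform table, each symbol on a single probe set, and 2021 without one were left out of the gene analyses. Values were used as deposited. Genes with a mean over the 4 arrays at or above the median of all gene means (4.06) were kept, 11593 in all. Many values were exactly equal between arrays: 46.3% of kept genes had at least 1 tie among the 4 arrays and 3.30% had the same value on all 4.

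Each dose was compared with 0 Gy, and irradiated arrays with each other, as the log2 difference per gene, with counts of genes at 2-fold or more in each direction. No test is possible for these pairs of single arrays. For each array, genes were counted in which it stood 2-fold apart from each of the other 3 in a single direction. The share of genes whose 4 different values followed the order of dose was set against the 2 of 24 orders that chance gives if all are equally likely. Pearson and Spearman correlations across genes between the differences of each pair of doses were set against 100 simulations of arrays that share a control. limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg at 0.05) compared the 3 irradiated arrays with the 0 Gy array and fitted a straight line in dose, each with 2 residual degrees of freedom. In the first fit the lone 0 Gy array was assumed to vary like the irradiated arrays, and differences between doses counted as error. In the second, departures from a line counted as error. On simulated data with the same layout and 200 changed genes, the first fit recovered 16% of genes changed by 1 log2 unit, 52% at 2, 80% at 4 and 90% at 6, with 8 false calls. The second recovered 22%, 50%, 90% and 98%, with 7.

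Before the data were examined, 22 gene lists and 11 lists of cell type markers were written. Older symbols were updated where the annotation gave a single current symbol. For each list the median log2 difference, the members at 1.5-fold or more in each direction, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins were computed. In a check with lists of 20 randomly drawn genes, 2 of 40 lists with no added change fell outside the central 95% of random lists. Of lists shifted by 0.5, 20 of 20 fell above it. Randomly drawn lists match the random lists by construction, and the shift was large beside the spread of their medians. This check could therefore hardly fail, and it does not cover lists of genes that vary together, such as those of a pathway. Lists were also tested in both limma fits with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 33 lists. With an estimated correlation camera uses only the 2 residual degrees of freedom, so it could hardly call a list. Lists of plasma cell genes other than immunoglobulins and of multipotent progenitor genes were added after the first look at the data and before their own values were seen.

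Named genes follow a rule fixed before the data were examined, which leaves out clone-named and predicted genes, olfactory, vomeronasal and taste receptors, small RNAs and ribosomal RNAs, and immunoglobulin and T cell receptor segments. It takes the 10 highest and 10 lowest genes of each dose against 0 Gy, the 10 in each direction with the largest smallest difference at all 3 doses, up to 4 members per list and dose with the largest absolute difference, all sort markers and sex-linked genes, up to 10 genes past the threshold in each limma fit, and the 5 in each direction with the widest range among genes ordered with dose. The text gives a part of them. Exceptions are named where they occur.

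Alternatives were quantile normalization, median centring, cyclic loess, no filter, a stricter filter that kept 7729 genes, thresholds of 1.5-fold and 3-fold, the mean of the other 3 arrays as control, an intensity trend in eBayes, dose rank and the square root of the dose, leaving out each array in turn, and an estimated correlation in camera. Counts and correlations without immunoglobulin genes, and results over genes with 4 different values, were added after seeing the data. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9. Gene positions are from assembly GRCm38.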

Results

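Gene expression was measured in mouse long-term haematopoietic stem cells (HSCs), the bone marrow cells that sustain blood formation for life. Lineage-negative, c-Kit-positive, Sca-positive marrow cells were exposed to γ-irradiation at 0, 0.02, 0.1 or 0.5 Gy and transplanted into lethally irradiated mice. At 6 months after transplantation, long-term HSCs were sorted as lineage-negative, c-Kit-positive, Sca-positive, Flk2-negative, CD48-negative and CD150-positive cells. The gate as given names no donor marker, so descent from the transplanted cells is assumed. Total RNA from each dose was hybridised to 1 array, so there are no replicates and no spread within a dose. Whether RNA was pooled over several recipient mice is not stated. Every comparison of single doses below is a difference between 2 arrays with no test, and the number of arrays limits its precision. The median deposited log2 intensity over 25206 probe sets was 4.02 at 0 Gy, 4.07 at 0.02 Gy, 4.02 at 0.1 Gy and 4.01 at 0.5 Gy. The filter on low values kept 11593 of 23185 named genes by their mean, so a kept gene can lie below the filter level of 4.06 on single arrays, and differences that involve such a value have an uncertain size.

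Transcripts of the sorted markers were looked at first. Kit, the stem cell factor receptor, had log2 values of 10.16, 10.57, 10.40 and 10.12 at 0, 0.02, 0.1 and 0.5 Gy. Slamf1, which encodes CD150, had values of 7.67, 8.65, 7.16 and 7.77. Flt3, which encodes the excluded Flk2 receptor, had 4.46, 4.76, 5.44 and 4.76, and Cd48, also excluded, had 4.13, 3.08, 4.11 and 4.13. Cd34, a marker of progenitors downstream of the long-term HSC in the mouse, had 8.68 at 0 Gy, 7.79 at 0.02 Gy, 9.77 at 0.1 Gy and 9.70 at 0.5 Gy. The female-specific transcript Xist had 3.05 on each of the 4 arrays. The Y-linked gene Kdm5d had 6.26, 6.28, 6.64 and 6.14 at 0, 0.02, 0.1 and 0.5 Gy.

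The first question was how HSCs sorted after transplantation of irradiated cells differed from those sorted after transplantation of unirradiated cells. At 0.02 Gy, 288 genes were at least 2-fold higher and 180 at least 2-fold lower than at 0 Gy. At 0.1 Gy, 184 were higher and 311 lower, and at 0.5 Gy, 189 were higher and 349 lower. Between irradiated arrays, 551 genes were at least 2-fold different between 0.1 and 0.02 Gy, 564 between 0.5 and 0.02 Gy and 407 between 0.5 and 0.1 Gy. Immunoglobulin genes made up 46 of the 50 largest differences at 0.02 Gy, 34 of 50 at 0.1 Gy and 39 of 50 at 0.5 Gy. Of the 100 immunoglobulin genes kept, 73 were at least 2-fold higher at 0.02 Gy and 6 lower. At 0.1 Gy 10 were higher and 43 lower, and at 0.5 Gy 5 were higher and 60 lower. Immunoglobulin genes were singled out after their values were seen. The filter uses the mean over all arrays, so a gene bright on a single array can be kept. Of 185 variable segments measured, 60 reached a log2 value of 8 at 0.02 Gy alone. At 0 Gy alone 6 did, at 0.1 Gy alone 1 and at 0.5 Gy alone 0. The filter can therefore inflate the share of kept immunoglobulin genes that were higher at 0.02 Gy.

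**Figure D1:**
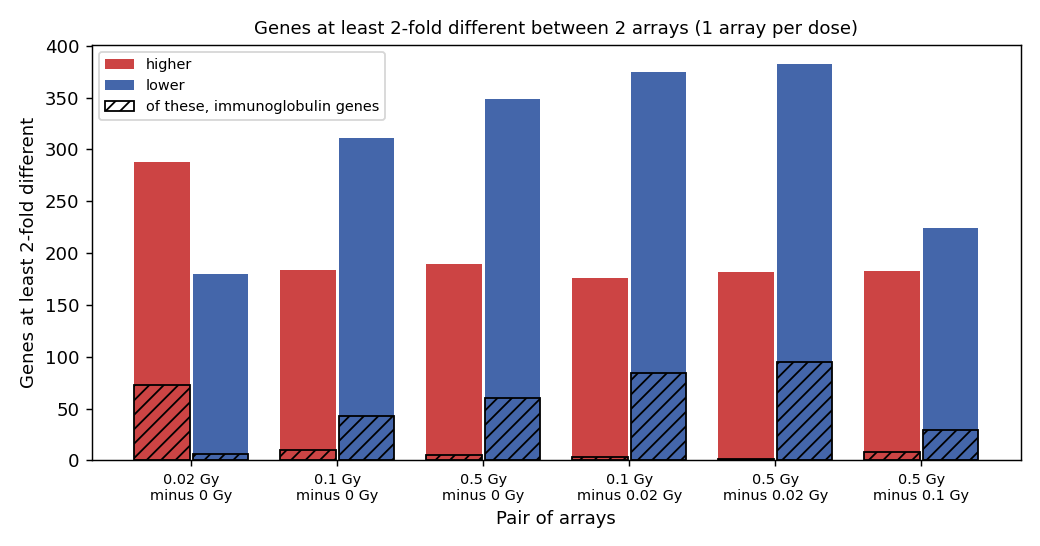
Number of genes at least 2-fold higher (red) or lower (blue) between 2 arrays, for the 3 doses against 0 Gy and the 3 pairs of irradiated arrays. Hatched parts are immunoglobulin genes. Total counts against 0 Gy, 468 to 538, lie within the range of the pairs of irradiated arrays, 407 to 564.

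At 0.02 Gy, lists of cell division genes had medians below 0 Gy, and the lists of the HSC signature and of the early response to stimuli had medians above it. Of 26 mitosis and proliferation genes, 11 were at least 1.5-fold lower and 0 higher, with a median log2 difference of -0.57. Plk1, a mitotic kinase, was 2.17-fold lower, Cdc20, an activator of the anaphase-promoting complex, had a difference of -0.96, and Ttk, a spindle checkpoint kinase, -0.92. Of 31 DNA replication genes, 8 were lower and 0 higher at this level, with a median of -0.35. They included the replication initiation factor Mcm10 at -0.99 and Gins1, a subunit of the replicative helicase, at -0.71. The 23 replication-dependent histone genes had a median of -0.33. Each of these medians lay at percentile 0 of 10000 expression-matched random lists.

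In the same array the immediate early genes, which respond to stimulation within minutes, had a median of 0.59, with 11 of 22 at least 1.5-fold higher and 0 lower. Examples were Egr2 at 1.84, Btg2 at 1.76 and Nr4a1 at 1.07. The 15 NF-kB and inflammatory genes had a median of 0.36, led by the neutrophil chemokine gene Cxcl2 at 1.86. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, was 3.50-fold higher, and 4 of the 21 p53 target genes were at least 1.5-fold higher and 0 lower, with a median of 0.02. The 32 long-term HSC signature genes had a median of 0.22, with 6 higher and 2 lower. Among the higher was Procr, which encodes the endothelial protein C receptor, at 1.38. The 27 aged HSC genes, which accumulate in stem cells of old mice, had a median of 0.35, with 6 higher, including Alcam at 1.53 and Nupr1 at 1.33, and 3 lower, including Neo1 at -1.09. B cell genes were on the same side as these lists, with a median of 0.93 over 7 genes and Cd79a, a subunit of the B cell receptor, at 6.61 against 3.80 at 0 Gy, the latter below the filter level. Over all 14 measured B cell genes the median was 0.10. The 8 neutrophil and granulocyte progenitor genes kept had a median of 0.50, with 3 higher and 1 lower, and the 12 erythroid genes -0.31, with 1 higher and 2 lower.

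Immunoglobulin genes and the other classes left out of naming aside, the highest genes relative to 0 Gy at this dose were Tfb2m, a mitochondrial transcription factor, at 4.09, the protocadherin gene Pcdhgb2 at 3.22 and the cytokine signalling inhibitor Socs3 at 3.03. Beside Cd79a, given above, Rcvrn at 2.94, Vldlr at 2.57, the transcriptional repressor Bcl6 at 2.56, Tgfbi at 2.43, Ctsw at 2.42 and Lsr at 2.39 followed. The lowest were Zfp991 at -2.78, Nipa1 at -2.77, the proteasome subunit gene Psma8 at -2.75, the metalloproteinase inhibitor Timp3 at -2.75 and the endothelial transcription factor Sox18 at -2.43. Tfb2m had a value of 2.90 at 0 Gy, below the filter level, as had Pcdhgb2 at 2.77.

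At 0.1 Gy, the HSC lists had medians below 0 Gy and the lists of granulocyte and erythroid genes had medians above it. Of the 32 long-term HSC signature genes, 12 were at least 1.5-fold lower and 0 higher, with a median of -0.22. They included the netrin receptor gene Neo1 at -2.86, the retinoic acid receptor gene Rarb at -2.45, the sulfotransferase gene Sult1a1 at -2.41 and the guanine deaminase gene Gda at -1.76. Of the 27 aged HSC genes, 14 were lower and 1 higher, with a median of -0.61. Clu, which encodes clusterin, was at -2.05 and Vwf, which encodes von Willebrand factor, at -1.44. The HSC signature and aged HSC lists share 6 genes. Both medians lay at percentile 0 of 10000 random lists.

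Of 8 neutrophil and granulocyte progenitor genes, 7 were at least 1.5-fold higher at 0.1 Gy and 0 lower, with a median of 2.39. Mpo, the myeloperoxidase of granule-forming progenitors, was 15.7-fold higher and S100a9 was at 2.84. Elane, neutrophil elastase, had 6.09, S100a8 6.54 and Ctsg 5.71, against 3.54, 3.89 and 3.48 at 0 Gy, all below the filter level. The filter, which uses the mean of all 4 arrays, kept 8 of the 20 measured members of this list. Over all 20 members, 8 were higher and 0 lower, and the median was 0.38. The 12 erythroid genes had a median of 0.51, with 6 higher and 1 lower. Klf1, the erythroid transcription factor, was at 1.39 and Car1, a red cell carbonic anhydrase, at 1.35. The 8 monocyte, macrophage and dendritic genes had a median of -0.63, with 5 lower and 0 higher, among them Cd68 and the class II invariant chain gene Cd74, both at -2.07. Over all 20 measured members of the monocyte, macrophage and dendritic list the median was 0.00. Multipotent progenitor genes, a list written after the first look at the data, had a median of 0.11 over 11 genes. The mitosis and proliferation genes had a median of 0.04 here, with 0 of 26 at least 1.5-fold different.

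The immediate early genes had a median of 0.21 at 0.1 Gy, with 6 of 22 at least 1.5-fold higher and 0 lower, and Fosb was at 1.40. Interferon-stimulated genes had a median of -0.24 over 28 genes, with 5 lower, including the GTPase gene Igtp at -1.41, and 0 higher. Other high genes were the TWEAK receptor gene Tnfrsf12a at 2.62, the differentiation inhibitor Id3 at 2.56 and Hnf4a at 2.51. The lowest genes beside those named, with the same classes left out, were Gimap4 at -3.75, Uxt at -3.33, the protease inhibitor gene Slpi at -3.01, the lymphotoxin gene Ltb at -2.99 and H2-DMb2, a chaperone of class II antigen presentation, at -2.77.

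At 0.5 Gy, the HSC lists again had medians below 0 Gy, and the lists of erythroid, granulocyte and lipid synthesis genes had medians above it. Of the 32 long-term HSC signature genes, 7 were at least 1.5-fold lower and 1 higher, with a median of -0.15. Neo1 was 8.70-fold and Rarb 6.07-fold lower, and the transcription factor gene Mycn was at -1.34. The aged HSC genes had a median of -0.52, with 13 of 27 lower and 2 higher. Of the 12 erythroid genes, 7 were higher and 0 lower, with a median of 0.65, among them Car1 at 1.92 and the erythroid transcription factor gene Gata1 at 1.12. The neutrophil and granulocyte progenitor genes had a median of 0.62, with 5 of 8 higher and 1 lower. Mpo was 4.89-fold higher and Elane had 6.28, while S100a9 was at -0.26. Over all 20 measured members of that list the median was 0.17. Multipotent progenitor genes had a median of 0.18.

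Immediate early genes had a median of 0.48 at 0.5 Gy, with 9 of 22 higher and 2 lower. Atf3 was at 1.10 and Klf6 at 0.98, whereas Egr2 was at -0.79. The NF-kB and inflammatory genes had a median of 0.36, with the chemokine gene Ccl4 at 1.55. Interferon-stimulated genes had a median of -0.28, with 6 of 28 lower and 1 higher, Isg15 being at -1.53. Of 18 lipid and cholesterol synthesis genes, 4 were higher and 1 lower, with a median of 0.30. These were the sterol pathway genes Idi1 at 1.56, Mvd at 1.02, Insig1 at 0.99 and Hmgcs1 at 0.71. Immunoglobulin genes and the other classes left out of naming aside, among the lowest genes was H2-DMb2, at 2.95 and so below the filter level, against 7.83 at 0 Gy. Nipa1 at -3.26, Gimap4 at -3.11, the eosinophil granule gene Prg2 at -3.10 and Smim40 at -2.92 were others. Eef1a1 at 3.04, Trappc2 at 2.73, Ifnz at 2.57, Lamtor3-ps at 2.45 and Eef1g at 2.39 were among the highest. Eef1a1 had a value of 3.78 at 0 Gy, low for a translation factor that is abundant in most cells.

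**Figure D2:**
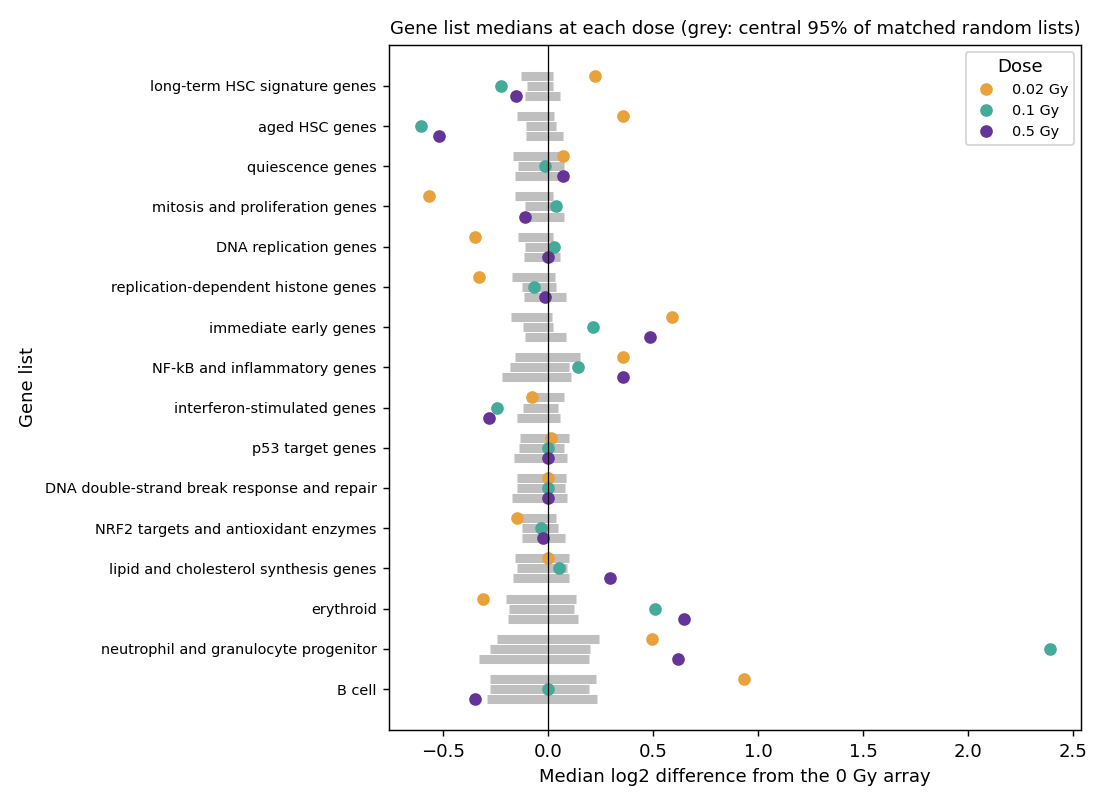
Median log2 difference from the 0 Gy array (horizontal axis) for 16 gene lists (vertical axis), 1 point per dose. Grey bars span the central 95% of 10000 expression-matched random lists. The mitosis list lies at -0.57 at 0.02 Gy, the aged HSC list at -0.61 at 0.1 Gy and -0.52 at 0.5 Gy, and the neutrophil list at 2.39 at 0.1 Gy. Medians are over the genes the filter kept, 8 of 20 measured for the neutrophil list and 7 of 14 for the B cell list.

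Several of the genes that led these comparisons are located as follows in assembly GRCm38. Mpo (Entrez gene 17523) lies on chromosome 11 from 87793784 to 87804412, and Elane (50701) on chromosome 10 from 79886312 to 79888216. H2-DMb2 (15000) lies on chromosome 17 from 34143229 to 34151553, within the major histocompatibility complex. Neo1 (18007) lies on chromosome 9 from 58874679 to 59036614, and Rarb (218772) on chromosome 14 from 16430839 to 17082331. Plk1 (18817) lies on chromosome 7 from 122159435 to 122169884, and Cdkn1a (12575) on chromosome 17 from 29090979 to 29100722.

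The medians of the lists for direct radiation damage were near 0. The 21 genes of DNA double-strand break response and repair had a median of 0.00 at each of the 3 doses. At 0.02 Gy 1 gene, the checkpoint kinase gene Chek1, was at least 1.5-fold lower, and 0 genes were beyond that level at 0.1 and 0.5 Gy. At 0.02, 0.1 and 0.5 Gy, 6, 5 and 7 of the genes had exactly the 0 Gy value. Above it lay 6, 7 and 7, and below it 9, 9 and 7, so the medians of 0.00 are tied values. The p53 target genes had medians of 0.02, 0.00 and 0.00 at 0.02, 0.1 and 0.5 Gy, with 1, 4 and 4 of 21 equal to the 0 Gy value. Of these 21 genes, 4 were at least 1.5-fold higher and 0 lower at 0.02 Gy, 3 were higher and 2 lower at 0.1 Gy, and 3 were higher and 3 lower at 0.5 Gy. Cdkn1a was at 1.81, 0.94 and 1.65, the kinase gene Plk3 at 1.45, 0.68 and 0.83, and Btg2 at 1.76, 0.07 and 0.65, whereas Trp53inp1 was at 0.40, -1.13 and -0.81. The 24 NRF2 targets and antioxidant enzymes had medians of -0.15, -0.03 and -0.03, with Srxn1, which encodes sulfiredoxin, at -0.62, -0.98 and -0.74. The 11 senescence-associated genes had -0.06, 0.00 and 0.04, and the 14 BCL2 family and apoptosis genes -0.10, -0.05 and -0.03. Within the latter, the anti-apoptotic genes Bcl2l2 and Bcl2l1 were at -1.16 and -0.97 at 0.5 Gy. The 18 quiescence genes had 0.07, -0.01 and 0.07.

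Other lists are given in the order 0.02, 0.1 and 0.5 Gy. Medians of the 20 heat shock and unfolded protein response genes were 0.08, 0.02 and 0.11, with the stress factor gene Ddit3 at 0.97, 1.37 and 1.14. The 17 TGF-beta pathway genes had 0.19, 0.00 and 0.14, with Id3 at 1.26, 2.56 and 2.26. Medians of 0.07, -0.08 and 0.00 were found for 22 autophagy and lysosome genes, and of -0.06, 0.00 and -0.13 for 31 DNA and histone modifying enzymes. Nuclear oxidative phosphorylation genes had -0.14, 0.00 and 0.04 over 34 genes, glycolysis genes 0.00, 0.00 and -0.09 over 15, and ribosomal protein genes -0.19, -0.02 and -0.02 over 27. Replication-dependent histone genes had -0.07 at 0.1 Gy and -0.01 at 0.5 Gy, and DNA replication genes 0.03 and 0.00. Among cell type markers, 8 T and NK cell genes had -0.06, 0.02 and 0.15, 5 lymphoid progenitor genes 0.30, 0.23 and 0.00, and 15 megakaryocyte and platelet genes -0.17, -0.15 and 0.00. The 3 basophil and mast cell genes had 0.00, 0.00 and 0.91, the 6 endothelial and stromal genes -0.56, -0.18 and -0.40, and the 3 sex-linked genes kept 0.02, 0.38 and -0.06. B cell genes had 0.00 at 0.1 Gy and -0.35 at 0.5 Gy, and the monocyte, macrophage and dendritic genes -0.25 at 0.02 Gy and -0.14 at 0.5 Gy. Over all 12 measured basophil and mast cell genes the median at 0.5 Gy was 0.06, and over all 14 B cell genes it was -0.03. Of the 99 medians of 33 lists at 3 doses, 18 at 0.02 Gy, 9 at 0.1 Gy and 14 at 0.5 Gy lay outside the central 95% of random lists. Under a stricter filter that kept 7729 genes, 8 of 30 lists lay outside at 0.5 Gy. Random lists do not carry the correlation between genes of a pathway, so these are not tests of dose.

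The second question was which genes were shared by all irradiated arrays. At all 3 doses, 39 genes were at least 2-fold higher and 53 at least 2-fold lower than at 0 Gy. The stricter filter gave 18 higher and 17 lower, and no filter 50 and 90, so the excess of lower genes depended on the filter. The higher genes with the largest smallest difference were Pcdhgb2 at 1.70, Mpo at 1.66, Pcp4l1 at 1.63 and Lamtor3-ps at 1.55, and the lower ones were Nipa1 at -2.67, Slc17a8 at -2.18, H2-DMb2 at -2.03 and Sox18 at -1.97. The chemokine genes Cx3cl1 and Ccl19 were also lower at all 3 doses, Ccl19 at -1.59, -2.23 and -2.21. All 3 comparisons share the single 0 Gy array, and 92 genes stood 2-fold apart from each other array at 0 Gy, compared with 167 at 0.02 Gy, 84 at 0.1 Gy and 109 at 0.5 Gy.

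In limma, the 3 irradiated arrays against the 0 Gy array gave 0 of 11593 genes past an adjusted p of 0.05, with 1260 at an unadjusted p under 0.05 and a smallest adjusted p of 0.157. Over the 6231 genes with 4 different values, an alternative chosen after seeing the data, 320 had an unadjusted p under 0.05 and the smallest adjusted p was 0.931. Adjusted over the list alone, 5 genes passed in 4 of the 33 lists: Rpl13, Bcl2l2, Pecam1, Cxcl12 and Eif2s3y. With no filter on low values 213 genes passed, 154 of them with 3 equal values on the irradiated arrays, which leaves no residual spread. Among lists tested with camera at the preset correlation, 3 passed an adjusted p of 0.05. Immediate early genes were higher on the irradiated arrays, with a median coefficient of 0.49. Interferon-stimulated genes were lower, with a median of -0.24, as were the endothelial and stromal genes, with -0.48. For each of these lists the medians at all 3 doses had the same sign, but all 3 subtract the same 0 Gy array, so this is not independent agreement. Some single irradiated arrays, set against the other arrays in the same way, also gave lists past this threshold. Those arrays differ in dose as well, and there is only 1 unirradiated array. Irradiation and variation between single arrays can therefore not be told apart as sources of such calls. The endothelial and stromal call rests on the 6 of 18 measured members that the filter kept, and over all 18 the median was -0.06 with an adjusted p of 0.182. With an estimated correlation none of the 3 lists passed. That setting uses only the 2 residual degrees of freedom and could hardly call a list, so this decides little.

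The third question was whether expression followed the dose. With the classes left out of naming set aside, the genes with the widest range among those ordered with dose were H2-DMb2, with values of 7.83, 5.80, 5.06 and 2.95 at 0, 0.02, 0.1 and 0.5 Gy, and Neo1, with 7.47, 6.38, 4.61 and 4.35. Rarb, the stromal and pericyte gene Cd248 and Pbx3 were also lowest at 0.5 Gy, at -2.60, -2.55 and -2.42 relative to 0 Gy. In the other direction stood Eef1a1, Elane, with 3.54, 4.09, 6.09 and 6.28, Spa17, Atp6v1g2 and Pycrl. Of 6231 genes with 4 different values, 225 were ordered upward and 341 downward with dose. This is 9.08% against the 8.33% that chance gives if all orders are equally likely. Genes vary together on an array, which can favour some orders without an effect of dose, so these shares are not tests of dose. Among the 1205 of these with a range of 2-fold or more, the share was 11.6%, with 45 upward and 95 downward. Rescaling the arrays breaks ties, so more genes can be ordered and the counts are not over the same genes. Of 11519 genes after quantile normalization, 815 were ordered upward and 273 downward, and of 11593, 767 and 283 after median centring and 739 and 470 after cyclic loess. Among genes with a range of 2-fold or more, 65 were ordered upward and 74 downward after quantile normalization, 69 and 77 after median centring, and 59 and 89 after cyclic loess.

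No gene passed an adjusted p of 0.05 in the limma fit of a straight line in dose (0 of 11593, 1425 at an unadjusted p under 0.05, smallest adjusted p 0.306). Over the 6231 genes with 4 different values, 402 had an unadjusted p under 0.05. Adjusted over the list alone, Insig1 and Bgn passed, 2 genes in 2 of the 33 lists, and in the multipotent progenitor list added later Cd27 passed at an adjusted p of 0.0494, named after its value was seen. In camera, 4 lists had an adjusted p of 0.0360: aged HSC genes, with a median slope of -1.18 log2 units per Gy, erythroid genes, with 1.25, lipid and cholesterol synthesis genes, with 0.21, and nuclear oxidative phosphorylation genes, with 0.23. The aged HSC medians against 0 Gy were 0.35, -0.61 and -0.52 in order of dose, and 0.12 between 0.5 and 0.1 Gy, so they did not fall steadily. Erythroid genes had -0.31, 0.51 and 0.65, below 0 Gy at the lowest dose. None of the 4 lists passed under the stricter filter. The oxidative phosphorylation genes did not pass after quantile normalization, with a slope of 0.26 and an adjusted p of 0.0727, or after cyclic loess, with 0.11 and 0.0923. With an estimated correlation none of the 4 passed (camera adjusted p = 0.953 for each). That setting uses only the 2 residual degrees of freedom and could hardly call a list, so this decides little. Long-term HSC signature genes passed after quantile normalization (camera adjusted p = 0.0433) and median centring (camera adjusted p = 0.0454) but not as deposited (camera adjusted p = 0.173). Interferon-stimulated genes passed after median centring only (camera adjusted p = 0.0457, against 0.0899 as deposited). The 0.5 Gy array has most of the leverage on these slopes.

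**Figure D3:**
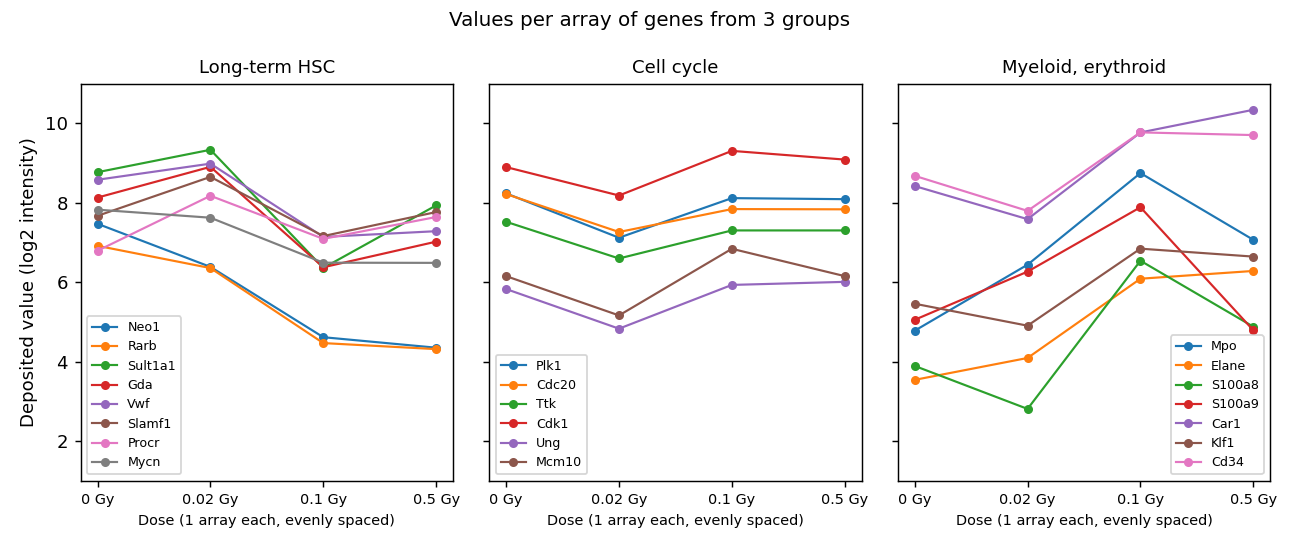
Deposited log2 intensity (vertical axis) of genes of long-term HSCs, the cell cycle and the myeloid and erythroid lineages at each dose (horizontal axis, evenly spaced), 1 array per dose. Neo1 has 7.47 at 0 Gy and 4.35 at 0.5 Gy, Plk1 is lowest at 0.02 Gy at 7.12, and Mpo is highest at 0.1 Gy at 8.75.

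Comparing the irradiated arrays with each other, the 0.02 Gy array differed from the other doses in the HSC and cell cycle lists. Between 0.1 and 0.02 Gy, 15 of 32 long-term HSC signature genes were at least 1.5-fold lower and 0 higher, with a median of -0.55, and between 0.5 and 0.02 Gy 13 were lower and 0 higher, with a median of -0.45. The mitosis and proliferation genes had medians of 0.64 and 0.50 in the same pairs, with 14 and 7 of 26 genes higher and 0 lower in both. Between 0.5 and 0.1 Gy the HSC list had a median of 0.10 and the mitosis list -0.07. The neutrophil and granulocyte progenitor genes had a median of -1.63 between 0.5 and 0.1 Gy, with 5 of 8 lower, and over all 20 measured members the median was -0.12. Immunoglobulin genes made up all 50 of the largest differences of the 0.1 and of the 0.5 Gy array from the 0.02 Gy array. Between 0.5 and 0.1 Gy they made up 24 of 50. Across genes, which are not independent replicates, the differences from 0 Gy had a Pearson r of 0.28 (Spearman rho 0.40) between 0.02 and 0.1 Gy, 0.25 (0.40) between 0.02 and 0.5 Gy and 0.64 (0.49) between 0.1 and 0.5 Gy. A shared control alone gave r of 0.50 to 0.51 in simulated arrays. Without immunoglobulin genes, an alternative chosen after seeing the data, r was 0.43, 0.45 and 0.56.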

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

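The test of the HSC signature between 0.1 and 0.02 Gy was chosen after its result was seen, and the remaining tests of this part were set out before theirs. Gene lists whose medians lay beyond 95% of random lists on opposite sides of 0 Gy at different doses were singled out, and these differences between doses were not tested, as each dose has 1 array. The long-term HSC signature genes differed by a median of -0.55 between 0.1 and 0.02 Gy and -0.45 between 0.5 and 0.02 Gy. The aged HSC genes differed by -0.78 and -0.66 in the same pairs. B cell genes differed by -1.83 between 0.5 and 0.02 Gy over the 7 genes kept and by -0.16 over all 14 measured, and over all 14 the 0.5 Gy median was within the central 95% of random lists. Erythroid genes differed by 0.31 between 0.1 and 0.02 Gy and by 0.70 between 0.5 and 0.02 Gy. Among the 935 probe sets above the filter level that carry no gene symbol and enter no comparison, 2 were at least 2-fold higher than at 0 Gy on all 3 irradiated arrays.

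Immunoglobulin genes differed most between arrays. Ighg1 had log2 values of 11.04, 12.55, 3.06 and 4.12 at 0, 0.02, 0.1 and 0.5 Gy, Igha 11.90, 12.47, 10.91 and 10.55, Igkc 12.66, 12.83, 12.29 and 11.70, and Jchain 9.75, 10.69, 8.46 and 7.32, all but Jchain named after their values were seen. As a test for an intensity-dependent trend left by the normalization, 100% of the immunoglobulin genes 2-fold different at 0.5 Gy stayed so after cyclic loess. The immunoglobulin genes had a median difference of -1.95 there. Over all kept genes the median difference was 0.02 after loess, so this test could hardly come out otherwise and decides little. RNA from plasma cells, which the exclusion of lineage-positive cells would be meant to remove, is a candidate explanation: the 17 plasma cell genes other than immunoglobulins had a median at percentile 1.39 of random lists at 0.5 Gy, 0.01 at 0.1 Gy and 100 at 0.02 Gy, with Mzb1 at 6.23, 7.60, 5.24 and 3.78. Of the 20 genes of that list measured, 14 lay above the filter level on all 4 arrays and 4 are in another list, and an effect of dose stays open and untested.

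The long-term HSC signature genes had a lower median at 0.1 Gy than at 0 Gy. After cyclic loess their median was still at percentile 0 of random lists. Those lists are matched on mean expression and gave percentile 0 before loess too, so this could hardly test for an intensity-dependent trend. What the percentile shows is a difference beyond that of genes of like mean expression. The median was -0.55 against the 0.02 Gy array, but with 1 array per dose this has no spread to be set against, so the 0 Gy array standing apart stays open. RNA from multipotent progenitors, which the Flk2-negative, CD48-negative and CD150-positive gate would be meant to remove, may contribute, as the multipotent progenitor genes lay at percentile 98.5 at 0.1 Gy. Their median there was only 0.11, it lay at percentile 69.8 between 0.1 and 0.02 Gy and at 93.5 among genes with 4 different values, and Cdk6 had 8.92 and 9.85 but Myb 10.13 and 10.13 at 0 and 0.1 Gy. Of the 12 genes measured, 11 lay above the filter level on all 4 arrays, so a small admixture would be hard to see, and a difference in the stem cells with dose stays open and untested.

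The immediate early genes had a higher median at all 3 doses than at 0 Gy. After cyclic loess the median at 0.02 Gy was 0.70. As deposited the list was already at percentile 100 of random lists matched on mean expression, so loess could hardly test for an intensity-dependent trend. The 0 Gy array alone standing apart stays open. The lowest percentile of the list over the 3 pairs of irradiated arrays was 0.12, between 0.1 and 0.02 Gy, which the test set out beforehand took as evidence against it. Random lists do not measure how single arrays vary, so that bound was wrong, and the medians of these pairs were only -0.13, -0.08 and 0.11. Handling of cells between sorting and lysis was not tested, because the labels give no times. With 1 array per dose, an effect of dose stays open and untested.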

How the results depend on the processing

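The alternatives without immunoglobulin genes and over genes with 4 different values were chosen after seeing the data. Under quantile normalization, median centring, cyclic loess and without immunoglobulin genes, all 6 counts of genes 2-fold different stayed within 1.5 times their value. A threshold of 1.5-fold gave 1466, 1505 and 1642 genes for 0.02, 0.1 and 0.5 Gy against 0 Gy, 1629, 1685 and 1440 for 0.1 and 0.5 Gy against 0.02 Gy and 0.5 against 0.1 Gy, and 411, 503, 384 and 473 for the 0, 0.02, 0.1 and 0.5 Gy arrays standing apart. At 3-fold, in the same order, they were 157, 159, 188, 224, 219 and 112, and 28, 82, 24 and 35. A stricter filter that kept 7729 genes gave 222, 255, 273, 286, 285 and 220, and 35, 76, 44 and 60, from fewer genes tested. No filter gave 140 genes for the 0 Gy array and 261 for the 0.02 Gy array standing apart, from more genes tested. With the mean of the other 3 arrays as control, 0.1 Gy gave 324 and 0.5 Gy 343. Among genes with a range of 2-fold or more, the share ordered with dose was 9.89% under quantile normalization and 11.6% as deposited. The Wilson interval of the latter, 9.93% to 13.6%, treats genes as independent, which they are not, so it does not measure the uncertainty. The cause of the change was not tested. In limma, irradiated against unirradiated arrays gave 213 genes with no filter, of which 154 had 3 equal irradiated values, 43 had a pair of equal values and 16 had none. It gave 0 genes under each other alternative, and the dose line 0 under all, leave-one-out fits included (0 to 0 in both). Camera calls for irradiated against unirradiated arrays numbered 5 under quantile normalization and 5 under median centring, 1 under the stricter filter and 0 with an estimated correlation. For the dose line they numbered 0 under the stricter filter and 0 with an estimated correlation, and the oxidative phosphorylation call was lost after quantile normalization and cyclic loess. An estimated correlation leaves camera only the 2 residual degrees of freedom, so it could hardly call a list. Why the other counts changed was not tested further. At all 3 doses, the stricter filter gave 18 genes 2-fold higher and 17 lower, and no filter 50 and 90. Correlations of differences without immunoglobulin genes were 0.43 and 0.45 for 0.02 Gy with 0.1 and 0.5 Gy. Lists outside the central 95% of random lists numbered 14 to 18 at 0.02 Gy, 9 to 12 at 0.1 Gy and 8 to 14 at 0.5 Gy over all settings, 8 being under the stricter filter, which left 30 lists. Of 579 list medians under alternatives, 438 moved by less than 1 SD of random lists, 140 moved by more, and 1 reversed. The reversal was of TGF-beta pathway genes at 0.5 Gy, at -0.0080 with no filter, and its cause was not tested. The moves were uneven: over genes with 4 different values 48 medians moved by more and 45 by less. Those that moved by more numbered 19 after quantile normalization, 12 after median centring and 11 after cyclic loess. They numbered 25 with no filter and 25 under the stricter filter. All 1452 differences of named genes under the 3 normalizations moved by less than the robust SD of their comparison. Taking the brightest probe set of a gene gives no other value, since each gene has 1. No paired analysis was possible because each dose has 1 array and nothing in the labels pairs them. No measure of background or detection was used. Differences that involve values near or below the filter level are of uncertain size, which limits genes such as Tfb2m, Pcdhgb2 and Eef1a1.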

Other observations

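The variable segments of immunoglobulins differed between arrays in which segments were bright. Of 185 heavy and light chain variable segments measured, 27 had a log2 value of 8 or more at 0 Gy, 86 at 0.02 Gy, 11 at 0.1 Gy and 2 at 0.5 Gy. Of these, 60 reached that level at 0.02 Gy alone, 6 at 0 Gy alone, 1 at 0.1 Gy alone and 0 at 0.5 Gy alone. Among constant regions, Ighm had 10.93, 11.20, 11.35 and 7.21 at 0, 0.02, 0.1 and 0.5 Gy, and Ighg3 had 2.95, 2.88, 2.88 and 2.86. The plasma cell genes other than immunoglobulins had medians of 0.31, -0.32 and -0.20 at 0.02, 0.1 and 0.5 Gy. These genes and the level of 8 were chosen after their values were seen.

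MicroRNAs and other small RNA genes were variable as a class. Of 174 kept, 19 were at least 2-fold different from 0 Gy at 0.02 Gy, 38 at 0.1 Gy and 41 at 0.5 Gy. These were 10.9%, 21.8% and 23.6% of the class, compared with 4.04%, 4.27% and 4.64% of all kept genes, a comparison not matched on expression. Between irradiated arrays the share of the class was 19.0% for 0.1 against 0.02 Gy, 18.4% for 0.5 against 0.02 Gy and 18.4% for 0.5 against 0.1 Gy. Of the genes for class II antigen presentation that were named, Cd74 had 9.94, 9.68, 7.87 and 9.23 and H2-Aa 9.35, 8.93, 8.14 and 9.25 at 0, 0.02, 0.1 and 0.5 Gy, both lowest at 0.1 Gy. H2-DMb2 had its lowest value, 2.95, at 0.5 Gy. Slpi was highest at 0.02 Gy, at 11.56, and lowest at 0.1 Gy, at 6.48.

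Each array was also set in turn against the other 3. In limma, 0 genes passed for the 0 Gy array, 1 for 0.02 Gy, 0 for 0.1 Gy and 0 for 0.5 Gy, with 1260, 1433, 1125 and 1532 genes at an unadjusted p under 0.05. In camera at the preset correlation, 3 of 33 lists passed for the 0 Gy array, 9 for the 0.02 Gy array, 5 for the 0.1 Gy array and 0 for the 0.5 Gy array. The immediate early genes passed for the 0 Gy array, where they were lower, and for the 0.02 Gy array, where they were higher (limma camera adjusted p = 0.00322). With an estimated correlation no list passed for any of the 4 arrays, the immediate early genes included. That setting uses only the 2 residual degrees of freedom and could hardly call a list, so this decides little. The mitosis, DNA replication, histone, HSC signature and aged HSC lists were among those that passed for the 0.02 Gy array at the preset correlation. Of the 935 unnamed probe sets above the filter level, 2 were at least 2-fold lower than at 0 Gy on all 3 irradiated arrays.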
